A study of Arabidopsis thaliana with 48 samples.

How the data were processed

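The samples were nuclear and cytoplasmic fractions of rosettes of 14-d-old Arabidopsis thaliana plants, of Col-0 and of tho5ab, grown in long days and kept at 21 °C or held at 37 °C for 3 h without recovery, per the labels' protocols. Fractions were separated by differential centrifugation, RNA was purified with the RNeasy Plant Mini kit, and ERCC spike-in RNA was added, per the labels' protocols. Libraries were made with the NuGEN Universal Plus RNA-Seq kit with NuQuant and depletion of Arabidopsis rRNA, per the labels' protocols. Reads were aligned to TAIR10 with STAR 2.7.8a and processed with Picard, UMI-tools and featureCounts, per the submitters' processing notes, which give neither their order nor the settings for strand and for reads with several positions. The deposited table holds raw counts per gene, 1 column per library, for 27420 genes, of which 27419 are protein coding. All 27420 identifiers matched the reference annotation. The table has 0 spike-in and 0 organelle genes, so scaling to spike-ins and shares of organelle, ribosomal and small nuclear RNA were not analysed here.

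Groups were taken from the sample labels: 8 groups of genotype, fraction and temperature, with 6 libraries each. No library was left out. Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, genes kept by filterByExpr over the 8 groups (17981 genes) and 1 mean per group. A prior count of 2 was used for log2 CPM values only. Log2 fold changes of the fit used edgeR's default prior count, on which their size depends where a group lies near 0 counts. All 48 libraries shared 1 estimate of spread, and 18 contrasts were tested with the quasi-likelihood F test. P-values were adjusted by Benjamini and Hochberg over the tested genes of each contrast, with a threshold of 0.05. Levels are CPM, counts relative to TMM-scaled library totals. A fold against a group with 0 counts in all libraries is a lower bound against 3 counts over the group. Floors and the limit for THO5B in 1 library cover counting error only, and the interval of the intronless difference within bins comes from 100 bootstrap draws of genes.

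There were 21 gene lists written before the data were examined: abscisic acid and water deficit; anthocyanin and flavonoid synthesis; cell division; circadian clock; cytosolic ribosomal proteins; flowering; heat shock transcription factors; HSP70, HSP90 and HSP100 chaperones; markers of guard cell, phloem, root and shoot meristem; other heat response genes; oxidative stress; photosynthesis; salicylic acid and defence; serine/arginine-rich splicing factors; small heat shock proteins; THO complex and mRNA export factors; trans-acting siRNA precursors and targets (of which the 6 precursors are not in the table); and the unfolded protein response. The 19 lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 19 lists of a contrast, and again with an estimated correlation.

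Intronless genes and genes with introns, and short transcripts (at most 1312 bp) and long ones (at least 2381 bp), were compared per library as the difference of their mean log2 CPM. Groups of 6 were compared by a two-sided exact permutation test (scipy 1.17.1) and interactions by a permutation test with 100000 resamples. The latter exchanged genotypes within each fraction, so it also removes a genotype effect shared by both fractions. Genes named were chosen by a rule written before the data were examined. It takes THO5A and THO5B in every group. It takes up to 5 genes with the highest and 5 with the lowest log2 fold change of each contrast, among protein-coding genes past the threshold with an absolute change of at least 1, a mean log2 CPM of at least 3, a symbol, and, between 2 groups, no overlap of their libraries. It takes up to 2 highest and 2 lowest members of each list in each contrast described, and further members of lists of at most 25 where a count needs them. The rule named 311 genes, and a gene named in 1 contrast was followed in others. Genes were marked as uncertain where their span overlaps another gene, or where blastn 2.17.0+ found another transcript with at least 95% identity over at least 25% of their length.

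Counts on opposite strands differed between libraries, and whether counting or library making caused it is not known. In 16 of the 48, genes lying wholly inside a gene on the opposite strand had far more counts relative to that gene than in the other 32 (81 such genes, host mean of at least 50 CPM). Since the strand setting is not stated, genes with such an overlap (6752 in the table) cannot be separated from their partner. The alternatives tried were DESeq2 1.42.0 size factors in the edgeR fit, DESeq2's Wald test, no filter on low counts, only the groups compared, each replicate number left out, the replicate number as a block, a covariate for the 16 libraries, the 32 others alone, and tho5ab without its replicate 7 at 37 °C. The last 3 were chosen after seeing the data. Tested on simulated data, the edgeR fit recovered 46, 65 and 27 of 100 changes of 2-fold, and 77, 93 and 68 of 100 of 4-fold, between genotypes in cytoplasm at 21 °C (17575 genes), in nuclei at 37 °C (17563) and for genotype by compartment at 37 °C (17563), so that many changes of 2-fold are missed. Of calls there 6.1%, 3.7% and 3.1% were false. Each gene was simulated with 1 spread in all 48 libraries, as the fit assumes. These shares therefore do not hold if the real fractions differ in spread. Tables were handled with python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.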

Results

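RNA was counted per gene in nuclear and cytoplasmic fractions of Arabidopsis thaliana rosettes, from the wild type Col-0 and from tho5ab, a double mutant of both genes for subunit 5 of THO, a complex that joins mRNA during synthesis and takes part in its export. Plants stayed at 21 °C or spent 3 h at 37 °C. The design gives 8 groups of genotype, fraction and temperature with 6 libraries each, 48 in all, and the series asks about export defects in tho5ab under heat. Total counts ran from 1025185 to 2174279 per cytoplasmic library and from 2601946 to 19914838 per nuclear library. Between 14665 and 17678 genes had at least 1 count in a cytoplasmic library, against 21413 to 25610 in a nuclear library. Of 27420 genes in the table, 17981 passed the filter on low counts and were tested. Levels are CPM, counts relative to the library's total scaled with TMM, as the mean ± SD of 6 libraries. Log2 fold changes come from edgeR's quasi-likelihood fit, which gives no standard error for them. Their ± is an approximate standard error (SE), the absolute change divided by the square root of its F value. Where a group has few counts, this SE may understate the uncertainty. Genes described as uncertain overlap another gene, on the opposite strand unless stated, or have a near-identical copy, so that reads could have been split between them. Positions are those of TAIR10.

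The mutated genes come first, since they check the labels. THO5B (AT1G45233, chromosome 1, 17152896 to 17154843, forward strand) had 0 counts in all 12 cytoplasmic tho5ab libraries. Against Col-0 cytoplasm, at 4.65 ± 4.37 CPM at 21 °C and 6.65 ± 3.85 CPM at 37 °C, that is at least 9.08-fold and at least 11.9-fold lower, with a floor of 3 counts over the group. In nuclei THO5B fell by 2.49 ± 0.64 on the log2 scale at 21 °C (from 6.16 CPM; edgeR adjusted p = 0.0037) and by 5.63 ± 0.78 at 37 °C (from 4.83 to 0.128 CPM). At 21 °C the 3 tho5ab nuclear libraries with high opposite-strand counts held 1.76 to 3.01 CPM of THO5B and the other 3 held 0.0629 to 0.15 CPM. Without replicate 5, whose Col-0 library held 13.5 CPM, the call in the cytoplasm at 21 °C was lost (adjusted p = 0.07 by edgeR), and without that library the Col-0 mean was 2.89 CPM and the bound 5.64-fold. THO5A (AT5G42920, chromosome 5, 17205971 to 17209650, reverse strand) was not lower in every group. Its level in tho5ab nuclei was 98.5 ± 18.3 CPM at 21 °C, 1.52 ± 0.36 above the 34.3 ± 2.55 CPM of Col-0 on the log2 scale. At 37 °C Col-0 nuclei held 185 ± 11.8 CPM and tho5ab nuclei 39.8 ± 39.6 CPM, a difference of -2.22 ± 0.36 (edgeR adjusted p = 2.4e-06). The tho5ab mean rests largely on replicate 7 at 118 CPM; the other 5 libraries had a mean of 24.1 CPM. The cytoplasm gave log2 differences of 0.04 ± 0.48 at 21 °C and -1.02 ± 0.49 at 37 °C, neither past the threshold. Without the tho5ab libraries of replicate 7 at 37 °C the latter passed it (-1.91, edgeR adjusted p = 0.0019). Reads of these genes in tho5ab do not check an insertion, because counts per gene do not show where in the transcript they lie.

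**Figure D1:**
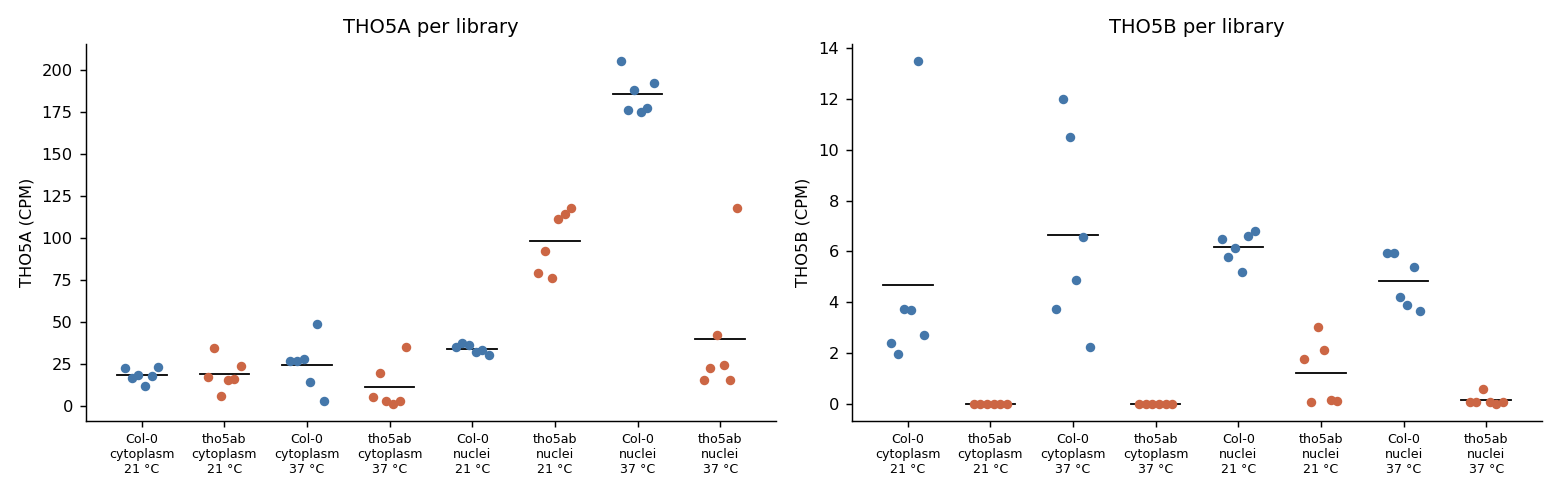
Each point is the level of THO5A (left) or THO5B (right) in one library, in CPM, over the 8 groups of 6 libraries, and black lines are group means. THO5B lies at 0 in all 12 cytoplasmic tho5ab libraries, while THO5A in tho5ab nuclei lies above Col-0 at 21 °C and has a lower mean at 37 °C.

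Nuclei and cytoplasm were compared to show what each fraction held. MT2B, a metallothionein gene, stood at 2332 ± 421 CPM in the Col-0 cytoplasm and 13.8 ± 4.79 CPM in nuclei at 21 °C (-7.39 ± 0.26, edgeR adjusted p = 1.6e-30). All 23 tested photosynthesis genes were lower in nuclei in both genotypes at both temperatures, as LHCB5, a light-harvesting protein of photosystem II, at -5.11 ± 0.21 in Col-0 at 21 °C. The 15 cytosolic ribosomal protein genes were lower too, all of them in 3 of the 4 comparisons and 14 of them in tho5ab at 37 °C. NF-YC12, a subunit of a CCAAT-binding transcription factor, was 7.45 ± 0.67 higher in nuclei, at 32.7 CPM against 0.164 CPM. The latter lies under a floor of 3 counts over the group, so the size of this change is uncertain. FRL2, a FRIGIDA-like gene, was at least 29-fold higher, against a floor of 3 counts over the Col-0 cytoplasm. At 37 °C all 16 tested genes of the small heat shock protein list were lower in nuclei of either genotype. HSP18.2, which is not in that list, gave -6.24 ± 0.27 in Col-0. Of 12 HSP70, HSP90 and HSP100 chaperone genes, 9 were lower in Col-0 nuclei at 21 °C, 9 lower and 2 higher in tho5ab nuclei at 21 °C, and 11 and 12 lower at 37 °C. Such directions rest on scaling that no spike-in could check. TMM factors at 37 °C were 1.24 to 1.34 in tho5ab nuclei and 0.45 to 0.64 in tho5ab cytoplasm. Before scaling HSP70 had the reverse order, as in replicate 1, with 557385 of 19009818 nuclear and 42564 of 1878101 cytoplasmic counts.

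In numbers, 12040 genes differed between the fractions of Col-0 at 21 °C by edgeR (7000 higher in nuclei) and 11072 at 37 °C (5868 higher), against 12207 (7275 higher) and 11493 (6659 higher) in tho5ab. The photosynthesis and ribosomal protein lists were lower in nuclei in all 4 comparisons by limma's camera with a preset and with an estimated correlation. When adjusted over the list alone, their counts were the same, except for 1 ribosomal protein gene that was then higher in tho5ab nuclei at 37 °C. Chaperones were lower by the preset test in all 4 (adjusted p = 3.82e-07 in Col-0 and 8.7e-05 in tho5ab at 21 °C), and in tho5ab at 21 °C the call was lost (adjusted p = 0.0917 with an estimated correlation). The median of all genes lay between 0.24 and 0.48 on the log2 scale in these 4 comparisons, and with DESeq2's size factors it moved to between 0.74 and 0.85; the share of calls higher in Col-0 nuclei went with it, from 58.1% to 68.3% at 21 °C and from 53.0% to 68.1% at 37 °C.

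Heat changed about as many transcripts in tho5ab as in Col-0. HSP17.6II, a cytosolic small heat shock protein of class II, had 0 counts in the Col-0 cytoplasm at 21 °C and 6981 CPM at 37 °C, at least 13300-fold higher against 3 counts over the group. The same gene was at least 21500-fold higher in the tho5ab cytoplasm. APX2, a cytosolic ascorbate peroxidase, was at least 1020-fold higher in Col-0 and at least 903-fold higher in tho5ab cytoplasm. Among genes that the naming rule could rank, the largest rises in Col-0 nuclei were those of HSP21 (12.46 ± 0.40) and HSP22.0 (12.43 ± 0.35). These are small heat shock proteins of the plastid and of the endoplasmic reticulum. All 16 tested small heat shock protein genes rose in each fraction of each genotype. HSP70 (AT3G12580, chromosome 3, 3991117 to 3993886, reverse strand) rose by 7.89 ± 0.19 in Col-0 and 8.26 ± 0.19 in tho5ab cytoplasm, and by 7.11 ± 0.18 and 8.68 ± 0.19 in nuclei. Of the 12 chaperone genes 11 rose in every group, and 1 fell in the Col-0 cytoplasm. Of 19 other heat response genes at least 18 rose in each group, and of 14 genes of the unfolded protein response at least 13, among them BIP3, an HSP70 of the endoplasmic reticulum (5.96 ± 0.96 in Col-0 cytoplasm). HSFA2, a heat shock factor, rose by 8.01 ± 0.40 in Col-0 cytoplasm and 9.42 ± 0.35 in tho5ab nuclei; its list of 17 gave 9 higher and 1 lower in Col-0 cytoplasm, 7 and 1 in Col-0 nuclei, 8 and 1 in tho5ab cytoplasm, and 11 and 1 in tho5ab nuclei.

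Transcripts that fell included ACD6, a regulator of defence (-6.23 ± 0.75 in Col-0 cytoplasm, -6.41 ± 0.54 in Col-0 nuclei, -5.96 ± 0.52 in tho5ab nuclei), and HMGB2, a chromatin protein, from 801 to 24.4 CPM in Col-0 cytoplasm (-5.03 ± 0.19). DFR and LDOX, enzymes late in anthocyanin synthesis, fell by 5.88 ± 0.65 and 5.89 ± 0.66 in Col-0 nuclei. Their list of 14 had 9 lower in Col-0 cytoplasm, 9 in tho5ab cytoplasm and 11 in nuclei of each genotype. The 23 photosynthesis genes went different ways in the fractions: 20 fell in Col-0 cytoplasm and 14 in tho5ab cytoplasm, where 1 rose, while in nuclei 11 rose and 5 fell in Col-0, and 13 rose and 5 fell in tho5ab. LHCA4, an uncertain gene for a light-harvesting protein of photosystem I, fell by 0.98 ± 0.15 in Col-0 cytoplasm and rose by 2.16 ± 0.15 in Col-0 nuclei. Of 15 cytosolic ribosomal protein genes 12 rose in Col-0 nuclei and 13 in tho5ab nuclei. Genes of cell division, 13 in the list, fell in 8 cases in Col-0 cytoplasm, 8 in Col-0 nuclei, 5 in tho5ab cytoplasm and 9 in tho5ab nuclei, with KN, a syntaxin of cell plate formation (uncertain), at -2.23 ± 0.42 in Col-0 cytoplasm.

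By edgeR, heat changed 7976 genes in Col-0 cytoplasm (4433 higher), 8212 in Col-0 nuclei (3940 higher), 7574 in tho5ab cytoplasm (3983 higher) and 9370 in tho5ab nuclei (4505 higher). Limma's camera called the 5 lists of heat shock, chaperone, heat factor and unfolded protein response genes higher in every group with the preset and the estimated correlation. Photosynthesis was lower in Col-0 cytoplasm by the preset test only (adjusted p = 0.0914 with an estimated correlation; 21 lower when adjusted over the list alone), and likewise in tho5ab cytoplasm (adjusted p = 0.343 with an estimated correlation; 15 lower and 1 higher adjusted over the list alone). In Col-0 nuclei it was not called (adjusted p = 0.235), and in tho5ab nuclei its call as higher was lost (adjusted p = 0.56 with an estimated correlation). Anthocyanin synthesis was called lower in nuclei of both genotypes either way and in cytoplasm by the preset test only (adjusted p = 0.0534 in Col-0 and 0.0994 in tho5ab with an estimated correlation). Cell division was lower in 3 groups either way; in tho5ab cytoplasm it was not called (adjusted p = 0.0645). Ribosomal proteins were higher in nuclei either way, and not called in the cytoplasm (adjusted p = 0.27 and 0.892). Adjusted over the list alone, heat shock factors gave 9, 8, 8 and 11 higher with 1, 1, 2 and 1 lower in the same order, chaperones 12 higher in tho5ab cytoplasm, and the unfolded protein response 14 higher in Col-0 cytoplasm. DESeq2's size factors moved the median log2 change of all genes under heat, from 0.07 to -0.08 in Col-0 cytoplasm, from -0.06 to -0.16 in Col-0 nuclei, from -0.01 to -0.13 in tho5ab cytoplasm and from -0.07 to -0.24 in tho5ab nuclei. With them most calls in the cytoplasm were lower: the share of higher ones went from 55.6% to 45.9% in Col-0 and from 52.6% to 45.7% in tho5ab, so the counts do not settle which direction prevails. With only the groups compared heat gave 4807 genes in Col-0 cytoplasm, 13458 in Col-0 nuclei and 3696 in tho5ab cytoplasm.

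Among the comparisons of tho5ab with Col-0, the cytoplasm at 21 °C gave the fewest genes past the threshold. CYP97B3 (AT4G15110, chromosome 4, 8629647 to 8633118, reverse strand), a carotenoid hydroxylase of the P450 family, rose from 5.55 ± 4.68 to 60.3 ± 17.7 CPM (3.42 ± 0.29, edgeR adjusted p = 1e-11). JAL33, a jacalin-related lectin, fell from 121 ± 21.3 to 39.2 ± 8.17 CPM (-1.62 ± 0.25). Among 22 genes for THO and mRNA export factors 5 were higher and 2 lower. The higher ones included UAP56A, an RNA helicase that joins export adaptors to THO (0.77 ± 0.16; uncertain, near-identical copy), and the export adaptors ALY1 (0.89 ± 0.12), ALY3 (1.01 ± 0.15) and ALY4 (1.26 ± 0.19), all 3 uncertain; SAC3A (-1.22 ± 0.30, uncertain) and THO5B were lower. Of 8 serine/arginine-rich splicing factors 3 were higher, SR30 (0.84 ± 0.17), SCL33 (0.53 ± 0.15) and SR45A (0.70 ± 0.16). The 12 chaperone genes had a median log2 difference of 0.18 and were not called as a list by limma's camera (adjusted p = 0.128), and neither were the 17 heat shock factors (0.361), 19 other heat response genes (0.361) and 16 small heat shock protein genes (0.0528), of which 1 was lower (HSP18.5, -1.34 ± 0.31).

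In the cytoplasm at 21 °C there were 644 genes past the threshold by edgeR, 289 higher and 355 lower. Limma's camera called the splicing factors higher (adjusted p = 0.000697; adjusted p = 0.0706 with an estimated correlation), the export factors higher (adjusted p = 0.0267; adjusted p = 0.385 with an estimated correlation) and photosynthesis, with 2 members lower, lower (adjusted p = 0.00902; adjusted p = 0.658 with an estimated correlation). When adjusted over the list alone, 3 splicing factors and 5 export factors were higher, and 3 export factors and 3 photosynthesis genes lower. In 6 of these 12 libraries, 3 of each genotype, genes nested on the strand opposite a host gene had unusually high counts; the other 6 alone gave 138 genes by edgeR, and the calls of SR30 (adjusted p = 0.11), SR45A (0.43), ALY4 (0.082) and SAC3A (0.14) were lost. With only the groups compared SR30 (edgeR adjusted p = 0.19), SR45A (0.36) and SAC3A (0.3) were lost too, as was SR45A without replicate 2 (0.076) or 4 (0.11), and SAC3A without replicate 1 (0.055), 2 (0.11) or 5 (0.06). Without replicate 4 the count was 425, with only the groups compared 80, and by DESeq2's Wald test 1765.

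Nuclei at 21 °C gave more genes past the threshold, in libraries with more counts, so these numbers alone do not rank the fractions. ADS1 (AT4G29140, chromosome 4, 14368877 to 14371195, forward strand), a MATE-type transporter gene without introns, rose from 31.4 ± 5.14 to 200 ± 8.56 CPM in tho5ab (2.67 ± 0.23, edgeR adjusted p = 1.7e-12). SOT12, a sulfotransferase, and CIPK25, a protein kinase that binds calcineurin B-like proteins, also without introns, rose by 2.65 ± 0.21 and 2.63 ± 0.32. SCPL13, a serine carboxypeptidase-like gene with 14 exons, fell from 52.2 to 9.93 CPM (-2.39 ± 0.30), and CYP708A2, a P450 of triterpene metabolism, gave -1.94 ± 0.42. Of 12 chaperone genes 11 rose without heat, HSP70 from 16.5 ± 2.11 to 53.7 ± 8.48 CPM (1.70 ± 0.14) and HSP70B, which has no intron, from 4.91 ± 0.217 to 18.1 ± 4.77 CPM (1.87 ± 0.26). Among the 17 heat shock factors 7 rose, with HSFA1A, a factor that starts the heat response, at 1.32 ± 0.26; among 19 other heat response genes 9 rose and 1 fell. Serine/arginine-rich splicing factors went the other way from the cytoplasm, with 6 of 8 lower, SCL33 at -0.81 ± 0.14 and SR30 at -0.77 ± 0.14. Of 23 photosynthesis genes 13 fell and 1 rose: LHCB5 at -1.19 ± 0.18 and PSAD1, a photosystem I subunit without introns, at 1.16 ± 0.16. Of 15 abscisic acid and water deficit genes 7 rose, among them the dehydrin COR47 (1.33 ± 0.15).

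In all 3866 genes passed by edgeR, 2283 higher and 1583 lower; the share of higher calls, 59.1%, was 51.2% with DESeq2's size factors and 43.8% by DESeq2's Wald test, which gave 7423 genes, and only the groups compared gave 8639. Chaperones (adjusted p = 3.63e-17), splicing factors (6.66e-06, lower), heat shock factors (0.0147), other heat response genes (0.00112) and the unfolded protein response, with 5 of 14 members higher (0.000365), were called by limma's camera and kept their call with an estimated correlation. Preset calls were lost for photosynthesis (lower, adjusted p = 0.183 with an estimated correlation), abscisic acid (0.0654), ribosomal proteins with 6 of 15 higher (0.209), export factors with 4 higher and 3 lower (0.234) and anthocyanin synthesis with 2 of 14 higher (0.36). Small heat shock proteins, with 5 of 16 higher, were not called (adjusted p = 0.0699). Adjusted over the list alone, counts among these differed for export factors (4 higher and 5 lower), the unfolded protein response (7 higher) and small heat shock proteins (5 higher and 1 lower).

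At 37 °C transcripts of most fixed heat lists were higher in the cytoplasm of tho5ab than in that of Col-0. HSP101, a disaggregase (uncertain), reached 43630 ± 6923 CPM against 14730 ± 1967 CPM (1.57 ± 0.18), and HSP90.2, a cytosolic HSP90, 13500 ± 2523 against 4398 ± 474 CPM (1.62 ± 0.14). HSP17.8-CI and HSP17.6A, cytosolic small heat shock proteins, were 1.64 ± 0.24 and 1.13 ± 0.22 higher. Of 12 chaperone genes 11 were higher, of 16 small heat shock protein genes 11 were higher and 1 lower (HSP15.4, -1.22 ± 0.27), and of 19 other heat response genes 9 were higher, including ROF1, an FKBP-type co-chaperone (1.03 ± 0.14). HSP70 itself was 0.45 ± 0.14 higher (edgeR adjusted p = 0.022), a call lost without replicate 2 (adjusted p = 0.083), 4 (0.058), 5 (0.069) or 6 (0.1) and in the 32 libraries with low opposite-strand counts (0.065). Outside the heat lists, NSP3, a nitrile specifier protein of glucosinolate breakdown, was 2.53 ± 0.39 higher, while TDT, the vacuolar dicarboxylate transporter, fell from 54.1 ± 12.5 to 13.1 ± 6.58 CPM (-2.03 ± 0.25) and RAC10, a small GTPase, by 1.99 ± 0.32. ARF3, an auxin response factor, was 2.63 ± 0.54 lower. NCED3, the enzyme that commits carotenoids to abscisic acid, was among 6 of 15 abscisic acid genes that were higher (2.39 ± 0.45), and ALY3 (1.47 ± 0.15, uncertain) among 6 of 22 export factor genes, where 2 were lower.

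In the cytoplasm at 37 °C 2533 genes passed by edgeR, 1146 higher and 1387 lower, and the share of higher calls went from 45.2% to 51.8% with DESeq2's size factors. The Wald test of DESeq2 gave 3839 genes and only the groups compared 1151. By limma's camera chaperones (adjusted p = 3.07e-25), other heat response genes (1.65e-07), small heat shock proteins (0.00141) and cell division, with 2 of 13 higher (0.00177), were called higher with either correlation. Heat shock factors, with 4 of 17 higher (adjusted p = 0.0646 with an estimated correlation), abscisic acid (0.064), splicing factors with 3 of 8 higher (0.0523), export factors (0.094), anthocyanin synthesis with 6 of 14 higher and 1 lower (0.305) and photosynthesis with 4 higher and 1 lower (0.563) lost theirs. When adjusted over the list alone, 12 small heat shock protein genes were higher and 2 lower, 11 other heat response genes higher and 1 lower, 4 cell division genes higher, 4 splicing factors higher, 7 export factors higher and 2 lower, and 7 photosynthesis genes higher and 1 lower; chaperones stayed at 11.

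Several of these genes were compared in nuclei at 37 °C next. HSP70 reached 22110 ± 2543 CPM in tho5ab against 2276 ± 591 CPM in Col-0 (3.28 ± 0.15, edgeR adjusted p = 1.4e-23), HSP70B 6470 ± 918 against 704 ± 225 CPM (3.20 ± 0.26) and HSFA2 2386 ± 272 against 418 ± 129 CPM (2.51 ± 0.26). HSP17.6C and HSP17.6A, with no introns, were 3.06 ± 0.31 and 2.79 ± 0.24 higher. Of 12 chaperone genes 11 were higher, of 16 small heat shock protein genes 12 were higher and 1 lower (HSP15.4, -1.22 ± 0.25), of 17 heat shock factors 13 were higher, and of 19 other heat response genes 11 were higher and 2 lower. HSP22.0, by contrast, differed by 0.08 ± 0.19. COR47 reached 7808 ± 920 against 1253 ± 167 CPM (2.64 ± 0.16) and was among 9 of 15 abscisic acid genes that were higher, with 1 lower. Outside these lists PELPK1, a gene for a repeat-rich cell wall protein without introns, rose from 6.42 ± 3.15 to 83.2 ± 40.0 CPM (3.70 ± 0.35). SNG1, the sinapoylglucose:malate acyltransferase, with 14 exons, fell from 343 ± 76.4 to 69.5 ± 12.2 CPM (-2.30 ± 0.23). Of 23 photosynthesis genes 11 were lower, LHCB5 by 1.19 ± 0.18, and 4 higher, with PSAD1 at 1.77 ± 0.16.

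**Figure D2:**
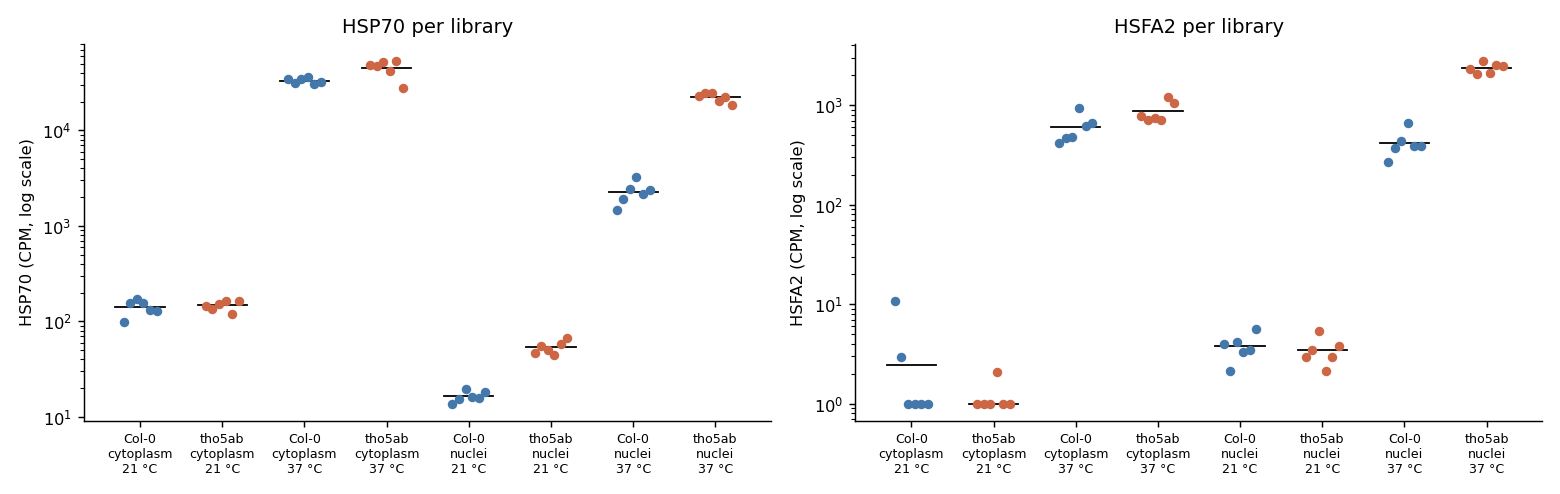
Each point is the level of HSP70 (left) or HSFA2 (right) in one library, in CPM on a log axis, with values under 1 drawn at 1 and black lines at the group means. In nuclei at 37 °C the 6 tho5ab libraries lie above the 6 Col-0 libraries for both genes.

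By edgeR 6193 genes differed in nuclei at 37 °C, 3335 higher and 2858 lower, a share of 53.9% higher that became 42.8% with DESeq2's size factors, which moved the median log2 change of all genes from -0.08 to -0.21. The Wald test of DESeq2 gave 9514 genes and only the groups compared 11355. Limma's camera called chaperones (adjusted p = 7.17e-18), small heat shock proteins (0.000106), heat shock factors (0.000374), other heat response genes (7.51e-06) and abscisic acid genes (6.28e-06) higher with either correlation. Photosynthesis was called lower (adjusted p = 0.568 with an estimated correlation), and the unfolded protein response with 6 of 14 higher (0.148) and ribosomal proteins with 6 of 15 higher and 1 lower (0.243) were called higher, by the preset test only. Adjusted over the list alone, 14 heat shock factors, 14 other heat response genes with 2 lower, and 10 abscisic acid genes with 1 lower were higher, and 13 photosynthesis genes were lower; with DESeq2's size factors 10 of the 17 heat shock factors were higher. Of the 2283 genes higher in tho5ab nuclei at 21 °C, 1711 were also higher at 37 °C, where independent lists would share 423.4, and 1167 were lower at both against 251.6; these comparisons share no library. Of the 4433 genes that heat raised in Col-0 cytoplasm, 1238 were higher in tho5ab nuclei at 37 °C against 822.2 for independent lists, and 643 lower against 704.6. Of the 3940 genes that heat raised in Col-0 nuclei, 293 were higher in tho5ab cytoplasm at 37 °C against 251.1, and 443 were lower against 303.9.

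The series' question, whether the mutant holds transcripts back in the nucleus, is closest to the difference between genotypes in nuclei minus that in cytoplasm. At 21 °C HSP70 shifted towards nuclei in tho5ab by 1.63 ± 0.20 and HSP90.1 by 1.78 ± 0.24, and 7 of 12 chaperone genes did so. Serine/arginine-rich splicing factors shifted towards the cytoplasm, 4 of 8, with SR30 at -1.61 ± 0.22 and SCL33 at -1.33 ± 0.21, and so did 6 of 22 export factor genes, with UAP56A at -1.76 ± 0.21 (uncertain). CYP97B3 gave -4.01 ± 0.36. At 37 °C HSP70 shifted towards nuclei by 2.83 ± 0.20, HSP70B by 3.01 ± 0.34, COR47 by 2.68 ± 0.22 and EMB3120, a gene without introns, by 4.03 ± 0.38, with 88.3 CPM in tho5ab nuclei. The chaperones as a list did not: 4 shifted towards nuclei and 3 towards the cytoplasm, among them HSP101 (-0.77 ± 0.25, uncertain) and HSP90.2 (-0.74 ± 0.19). Both calls were lost without replicate 4 (edgeR adjusted p = 0.12 and 0.09), and that of HSP101 also without replicate 2 (0.081), 5 (0.092) or 6 (0.089). Of 16 small heat shock protein genes 5 shifted towards nuclei and 1 towards the cytoplasm. In the unfolded protein response 8 of 14 shifted towards nuclei, with BIP2 (1.59 ± 0.28, uncertain, near-identical copy) and BZIP28, a transcription factor of that response (1.15 ± 0.26). Of 23 photosynthesis genes 12 shifted towards the cytoplasm and 1 towards nuclei, PSAD1 at 1.23 ± 0.23.

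This difference of differences passed for 1151 genes at 21 °C by edgeR (809 higher) and for 2641 at 37 °C (1776 higher). The libraries with low counts on opposite strands gave 517 genes at 21 °C, and at 37 °C DESeq2's size factors moved the share of higher calls from 67.2% to 49.5%. By DESeq2's Wald test 2616 and 4556 genes passed, and with the replicate number as a block fewer passed at 21 °C than in the main fit. Limma's camera called 4 lists at 21 °C with either correlation: chaperones (adjusted p = 3.51e-10), small heat shock proteins with 2 of 16 higher (0.00115), splicing factors (8.98e-11, lower) and export factors (0.000357, lower). Abscisic acid genes with 3 higher (adjusted p = 0.289 with an estimated correlation), the unfolded protein response with 1 higher (0.289) and photosynthesis with 1 higher and 2 lower (0.6) lost theirs. At 37 °C every preset call was lost: the unfolded protein response (adjusted p = 0.218 with an estimated correlation), photosynthesis (0.353), ribosomal proteins with 5 of 15 higher (0.282), splicing factors with 2 lower (0.282) and export factors with 2 higher and 5 lower (0.282). Chaperones (adjusted p = 0.797) and small heat shock proteins (0.246) were not called. When adjusted over the list alone, at 21 °C 9 chaperones and 6 small heat shock protein genes were higher, and 6 splicing factors and 8 export factors lower; at 37 °C 11 genes of the unfolded protein response were higher, 13 photosynthesis genes lower and 4 higher, and 4 chaperones lower and 4 higher.

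Whether heat acted differently in the mutant was tested within each fraction. In the cytoplasm 9 of 12 chaperone genes rose more in tho5ab than in Col-0, HSP101 by 1.72 ± 0.30 (uncertain) and HSP70-2 by 2.79 ± 0.42, as did 6 of 16 small heat shock protein genes and 6 of 19 other heat response genes, where 1 gave a lower value. In nuclei HSFA2 rose 2.63 ± 0.37 more in tho5ab and HSP70 1.58 ± 0.20 more, and 3 of 12 chaperones, 4 of 16 small heat shock proteins and 4 of 19 other heat response genes did so. GRP7, an RNA-binding protein of the clock's output, fell under heat in Col-0 nuclei (-1.58 ± 0.15) and rose in tho5ab nuclei (0.85 ± 0.15), a difference of 2.43 ± 0.22. RS31 gave 1.99 ± 0.28 and was among 3 of 8 splicing factors higher. THO5A gave -3.74 ± 0.51, and LAC7, a laccase, -2.86 ± 0.68.

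Genotype by heat passed for 723 genes in the cytoplasm (330 higher) and 663 in nuclei (451 higher) by edgeR. Limma's camera called chaperones (adjusted p = 5.19e-18 and 4.8e-08), small heat shock proteins (5.82e-06 and 0.000111) and other heat response genes (0.000157 and 0.000233) higher in cytoplasm and in nuclei with either correlation, and splicing factors in nuclei (6.36e-07). Lost with an estimated correlation were, in cytoplasm, abscisic acid genes with 2 higher (adjusted p = 0.327 with an estimated correlation), cell division (0.0869) and photosynthesis (0.516), and in nuclei abscisic acid genes with 2 higher (0.0846), heat shock factors with 2 higher (0.0618) and export factors with 4 higher and 1 lower (0.229). Adjusted over the list alone, 7 small heat shock protein genes were higher and 1 lower in cytoplasm and 6 higher in nuclei, and 5 splicing factors were higher in nuclei. Without replicate 1 the counts were 452 and 386, without replicates 5 and 6 the nuclear count was 419 and 410, and libraries with low opposite-strand counts alone gave 288 and 386. DESeq2's size factors moved the share of higher calls in nuclei from 68.0% to 55.9% and in cytoplasm from 45.6% to 53.0%. The counts were 124 in cytoplasm and 3795 in nuclei with only the groups compared, and 1869 and 2329 by DESeq2's Wald test, so they do not rank the fractions.

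Heat and compartment were compared within Col-0 alone. Small heat shock protein transcripts rose less in nuclei than in cytoplasm for 9 of 16 genes, with HSP17.6A at -4.57 ± 0.82, and so did 8 of 19 other heat response genes. HSP18.2, which is in neither list, gave -3.07 ± 0.43. Photosynthesis genes went the other way, 18 of 23 higher and 1 lower, with LHCA4 at 3.14 ± 0.21 (uncertain) and LHCB5 at 1.54 ± 0.25. Of 8 splicing factors 2 were higher and 3 lower, SR30 at -3.63 ± 0.22. By edgeR 2878 genes passed, 1325 higher and 1553 lower, a share of 46.0% higher that became 52.2% with DESeq2's size factors; the Wald test of DESeq2 gave 4641. Calls by limma's camera for small heat shock proteins (adjusted p = 1.96e-16), photosynthesis (6.15e-22), other heat response genes (0.00015) and splicing factors (0.000175) held with an estimated correlation, and that of ribosomal proteins with 7 of 15 higher was lost (adjusted p = 0.18 with an estimated correlation). When adjusted over the list alone, 9 small heat shock proteins were lower and 1 higher, and 19 photosynthesis genes higher and 2 lower.

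The interaction of genotype, heat and compartment passed for 342 genes by edgeR, 224 higher and 118 lower, a share of 65.5% higher that became 50.4% with DESeq2's size factors. GRP7 gave 2.58 ± 0.30. Of 12 chaperone genes 1 was higher and 4 lower (2 and 9 adjusted over the list alone). Its calls by limma's camera were lost with an estimated correlation: chaperones (adjusted p = 0.1), splicing factors with 2 higher (0.1), ribosomal proteins with 2 higher (0.607) and photosynthesis with 1 lower (0.677). Leaving out replicate numbers 1, 2, 3, 5 or 6 gave 190, 222, 202, 154 and 214 genes, low antisense libraries alone gave 124, and DESeq2's Wald test gave 1258. With the replicate number as a block fewer genes passed than in the main fit.

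Transcript classes were compared because THO acts on transcripts during synthesis and splicing. In Col-0 nuclei genes without introns lay below intron-containing genes, at -1.278 ± 0.169 at 21 °C and -1.221 ± 0.156 at 37 °C (mean log2 CPM over 2240 genes minus that over 15740, SD of 6 libraries). In tho5ab nuclei the values were -0.551 ± 0.148 and -0.624 ± 0.126, so that intronless transcripts were relatively higher by 0.727 (SE 0.092) and 0.597 (SE 0.082), with 6 of 6 tho5ab libraries above all Col-0 libraries at each temperature (exact permutation p = 0.00216 two-sided, the smallest of 924 permutations; Benjamini-Hochberg adjusted p = 0.00433 over 24 comparisons). The cytoplasm gave 0.030 at 21 °C (exact permutation p = 0.645) and -0.019 at 37 °C (exact permutation p = 0.812). Nuclear minus cytoplasmic genotype differences were 0.696 at 21 °C (permutation p = 0.00233 over 100000 resamples) and 0.615 at 37 °C (permutation p = 0.00105). Genotypes were exchanged within each fraction, so these p-values refer to no genotype effect in either fraction. In the 3 tho5ab and 4 Col-0 nuclear libraries at 21 °C with low opposite-strand counts the difference was 0.701. The 3 tho5ab libraries with high counts lay at -0.391, -0.403 and -0.460, and the 2 such Col-0 libraries at -1.096 and -1.031. Compared with their cytoplasm, intronless transcripts were lower in Col-0 nuclei (-0.444 at 21 °C and -0.304 at 37 °C) and higher in tho5ab nuclei by 0.252 and 0.311; among genes with a mean log2 CPM of at least 3 the values were -0.833 and -0.732 in Col-0 and -0.015 and 0.059 in tho5ab. Short transcripts, at most 1312 bp, lay further below long ones, at least 2381 bp, in nuclei than in cytoplasm, with differences from -1.862 to -2.063, and in nuclei at 37 °C tho5ab was 0.208 (SE 0.042) above Col-0 (exact permutation p = 0.00216), against 0.053 at 21 °C (exact permutation p = 0.448).

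**Figure D3:**
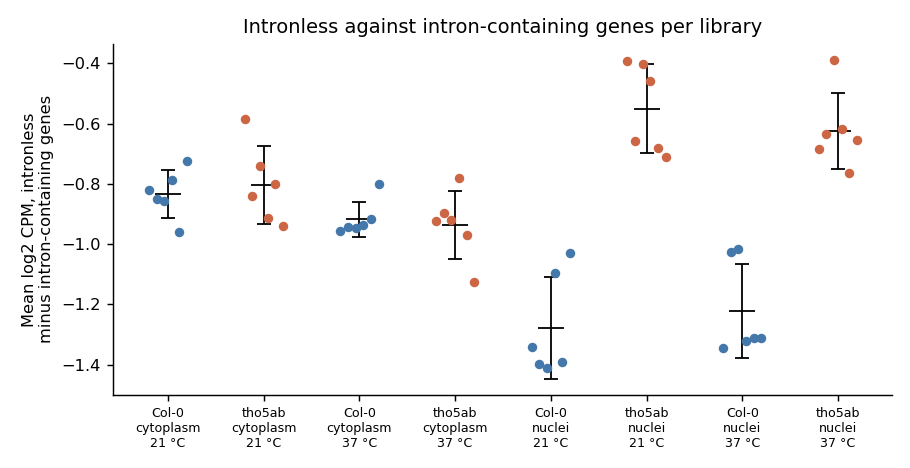
Each point is one library's mean log2 CPM of 2240 intronless genes minus that of 15740 intron-containing genes, with group mean and SD as black bars. Cytoplasmic groups of both genotypes overlap, while in nuclei all 6 tho5ab libraries lie above all 6 Col-0 libraries at 21 °C and at 37 °C.

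After these results were seen, genes were split by the highest number of exons of any annotated transcript. Median log2 differences between tho5ab and Col-0 nuclei at 21 °C fell from 0.71 for genes with 1 exon to 0.36, 0.14, -0.02, -0.18, -0.36 and -0.50 for 2, 3, 4 to 5, 6 to 10, 11 to 20 and over 20 exons. At 37 °C they ran from 0.55 to -0.57. The cytoplasm gave medians between 0.05 and -0.08 at 21 °C and between 0.02 and -0.15 at 37 °C. By edgeR 765 genes with 1 exon were higher and 19 lower in tho5ab nuclei at 21 °C, while of genes with over 20 exons 2 were higher and 205 lower; at 37 °C these counts were 807 and 45 against 4 and 261.

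**Figure D4:**
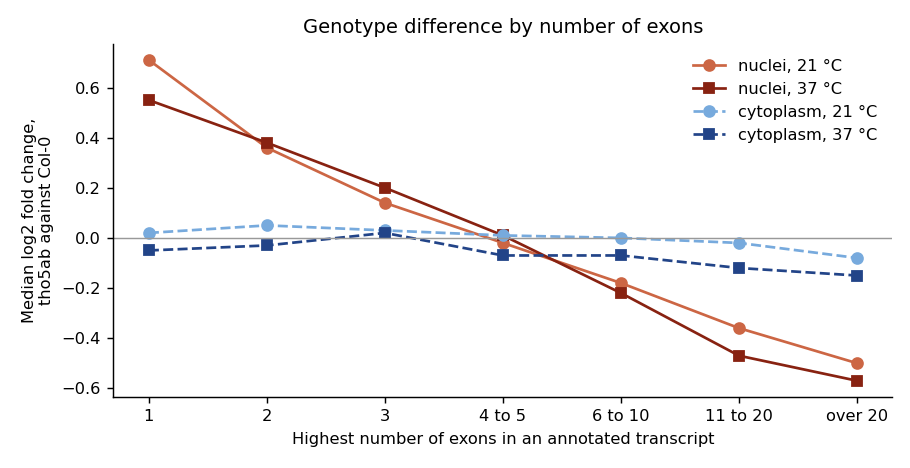
Lines join median log2 fold changes of tho5ab against Col-0 over genes grouped by their highest number of exons, for nuclei and cytoplasm at both temperatures, with 6 libraries per group. Nuclear medians run from 0.71 at 1 exon to -0.50 at over 20 exons at 21 °C, and cytoplasmic ones stay between 0.05 and -0.15.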

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

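The tests of explanations in this part were all chosen after the results were seen, and the interaction contrasts were planned.

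Transcripts of genes without introns were relatively higher in tho5ab nuclei than in Col-0 nuclei, by 0.727 at 21 °C. Within 122 bins of transcript length, GC content and level the median gap was 0.80 (95% interval 0.76 to 0.83), against 0.81 without bins, so these properties do not account for it. The 100 most abundant cytoplasmic transcripts took 4.27% of counts in tho5ab nuclei, 4.87% in Col-0 nuclei and 44.3% in tho5ab cytoplasm. This argues against cytoplasmic RNA left in the tho5ab nuclei as the cause. Over all genes tho5ab cytoplasm lay at -0.803, below tho5ab nuclei at -0.551. Among genes with a mean log2 CPM of at least 3 it did not, at 0.030 against 0.015, so this order alone excludes nothing. Among libraries with low opposite-strand counts alone the intronless difference between genotypes was 0.701. Export and turnover of these transcripts were not tested, and the cause is open.

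Heat response transcripts were higher in tho5ab nuclei than in Col-0 nuclei at 37 °C, with 47 of 64 genes of 4 heat lists higher and 3 lower, and their median lay 1.04 above that of all genes on the log2 scale, beyond what scaling by a few abundant transcripts would give. On TMM-scaled levels, carry-over of cytoplasm would need a median of 12.9% over the 47 higher genes. For 16 of them tho5ab cytoplasm did not exceed tho5ab nuclei, and the full share was entered. Applied to unscaled counts, this would put abundant transcripts that heat did not raise at 7%. Scaling differs between fractions, so the 12.9% and 7% do not hold as levels. Those transcripts took 4.29% of counts in tho5ab nuclei, 4.51% in Col-0 nuclei and 23.8% in tho5ab cytoplasm. Against genes with the same number of exons, the heat lists were still 0.960 higher in tho5ab (4.869 ± 0.060 against 3.909 ± 0.207, exact permutation p = 0.00216, 6 of 6 libraries above Col-0). In cytoplasm at 37 °C they were 0.873 higher as well (exact permutation p = 0.00216, 6 of 6 above), and counts per fraction do not separate synthesis, turnover and retention. Over 1154 genes that heat raised in Col-0 cytoplasm the difference was 0.177 in nuclei (exact permutation p = 0.0108, 5 of 6 above) and -0.227 in cytoplasm (6 of 6 below), where choosing the genes on those Col-0 libraries favours Col-0.

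THO5A stood at 118 CPM in replicate 7 of tho5ab nuclei at 37 °C, far from the other 5 libraries at 15.6 to 42.2 CPM. A share of Col-0 would have to be 58.2% and would bring 2.81 CPM of THO5B, and the upper limit was 0.269 CPM from 1 count. Plants that were not heated are excluded too, since 0.629% of 636 heat-raised transcripts (4 of them) lay nearer to the 21 °C mean. No biological explanation was tested.

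Some single libraries also lay far from the others of their group, in 10 of 70 groups of values tested. Chance gives about 3.5, but this does not hold for genes near 0 counts, where a few counts can stand apart. Of the 10, 5 fell on libraries with high opposite-strand counts, 4 of them the only such library of their group. THO5B stood at 13.5 CPM (15 counts) in replicate 5 of Col-0 cytoplasm at 21 °C. It stood at 0.554 CPM (4 counts) in replicate 4 of tho5ab nuclei at 37 °C. HSFA2 stood at 10.7 CPM (9 counts) in replicate 1 of Col-0 cytoplasm at 21 °C. In tho5ab cytoplasm at 21 °C it stood at 2.06 CPM in replicate 5, from 2 counts against 0 in the other libraries. Total counts were 1147881 in replicate 5 of tho5ab cytoplasm and 5834668 in replicate 4 of tho5ab nuclei at 37 °C. In replicate 7 of tho5ab cytoplasm at 37 °C 16321 genes were detected and the 10 highest genes took 26.6% of counts. The intronless difference was -0.802 in replicate 6 of Col-0 cytoplasm at 37 °C.

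Effects differed between groups by the interaction terms of edgeR. Genotype by compartment passed for 1151 genes at 21 °C and 2641 at 37 °C, and genotype by heat for 723 in cytoplasm and 663 in nuclei. Heat by compartment in Col-0 passed for 2878 genes, and the interaction of all 3 for 342.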

How the results depend on the processing

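The covariate for libraries with high opposite-strand counts, the 32 low antisense libraries only, and tho5ab without replicate 7 at 37 °C were chosen after the results were seen. Of 261 counts of genes under the alternatives, 225 stayed within 1.5 times and 36 moved further.

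With only the groups compared, heat gave 4807 genes in Col-0 cytoplasm, 13458 in Col-0 nuclei and 3696 in tho5ab cytoplasm; tho5ab against Col-0 gave 80 and 1151 in cytoplasm and 8639 and 11355 in nuclei at 21 and 37 °C; genotype by heat gave 124 in cytoplasm and 3795 in nuclei. DESeq2's Wald test gave 1765, 7423, 3839 and 9514 for tho5ab against Col-0 (cytoplasm and nuclei at 21 °C, then at 37 °C), 2616 and 4556 for genotype by compartment, 1869 and 2329 for genotype by heat, 4641 for heat by compartment and 1258 for the interaction of all 3. The low antisense libraries only gave 138 for cytoplasm at 21 °C, 517 for genotype by compartment at 21 °C, 288 and 386 for genotype by heat and 124 for the interaction of all 3. Several of these fits hold fewer libraries, which alone would not raise a count. With only the groups compared, the counts given fell in cytoplasm and rose in nuclei. The main fit shares 1 estimate of spread between both fractions, and whether that causes these moves was not tested. With each replicate number left out, or tho5ab without replicate 7 at 37 °C, counts ranged from 425 to 722 for cytoplasm at 21 °C, from 452 to 911 and from 386 to 683 for genotype by heat in cytoplasm and nuclei, and from 154 to 417 for the interaction of all 3; other contrasts stayed within 1.5 times.

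Both fractions of each genotype and temperature carry the same replicate numbers, but the labels do not say that they share plants. They were not taken as pairs in the main fit. Over 24 pairs of nuclei and cytoplasm, r ran from 0.00 to 0.24 (4608 genes), with 10 pairs at or below 0.1. Still, 32 of 48 libraries correlated best with their own number, where chance gives 8, a hint of pairing that the main fit leaves out. With the replicate block the counts were 695 for genotype by compartment at 21 °C and 180 for the interaction of all 3, and other counts stayed within 1.5 times. Of 342 list tests limma's camera called 142, 148 with the block (142 shared), 143 with the low antisense libraries (136 shared) and 81 with an estimated correlation, which widens the error of each list.

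Of 12932 values of genes past the threshold 12115 kept direction and side, 815 lost the threshold and 2 reversed; of 9778 values of genes not past it 433 passed and 4 reversed. Reversed were LUX between fractions of Col-0 at 21 °C (0.42 with DESeq2 size factors and with the Wald test) and, in low antisense libraries, CO in heat in Col-0 nuclei (-2.93) and between genotypes in nuclei at 37 °C (1.93), FAMA in heat in tho5ab cytoplasm (0.03) and PUM9 in heat by compartment in Col-0 (-1.07). For genes with a mean log2 CPM of at least 3, the intronless difference between nuclei and cytoplasm was -0.833 and -0.732 in Col-0 at 21 and 37 °C; in tho5ab it was -0.015 at 21 °C and 0.059 at 37 °C, no longer past the threshold. With the median over genes, the intronless difference under heat was -0.210 in Col-0 and -0.308 in tho5ab cytoplasm, now past it, and short minus long transcripts 0.097 and 0.209, no longer past it.

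Scaling to ERCC spike-ins, library sizes with organelle genes, and the share of nuclear-encoded counts were not run, since the table has no such genes. Depth limits genes with few counts in the cytoplasm, where libraries held 1025185 to 2174279 counts.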

Other observations

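The test of exon number was chosen after the result was seen, and the splits of samples were planned. Among lists not described so far, the phloem marker list was lower under heat in nuclei of Col-0 and in both fractions of tho5ab by limma's camera with either correlation, with 3 of 4 members lower in each, and in Col-0 cytoplasm by the preset test only (2 lower, 4 adjusted over the list alone; adjusted p = 0.0534 with an estimated correlation). Oxidative stress genes were higher under heat in all 4 groups with either correlation, 7 of 13 in Col-0 cytoplasm with 3 lower, 8 in Col-0 nuclei with 3 lower, 7 in tho5ab cytoplasm with 1 lower and 8 in tho5ab nuclei with 3 lower. Salicylic acid and defence genes were lower under heat by the preset test alone, 8 of 17 in Col-0 cytoplasm (limma's camera adjusted p = 0.0059; adjusted p = 0.198 with an estimated correlation) and 11 in tho5ab nuclei (adjusted p = 0.00861; adjusted p = 0.244 with an estimated correlation).

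The circadian clock list was higher in nuclei than in cytoplasm by the preset test, 13 of 16 members in Col-0 at 21 °C with 1 lower (limma's camera adjusted p = 0.00811; adjusted p = 0.122 with an estimated correlation), and was not called between genotypes in nuclei at 37 °C (2 higher, 6 lower, adjusted p = 0.192). Guard cell markers (1 of 4 higher, 3 adjusted over the list alone; limma's camera adjusted p = 0.415), root markers (adjusted p = 0.901) and targets of trans-acting siRNAs (1 of 5 higher and 3 lower, adjusted p = 0.274) were not called there either; the 6 precursors in the list of trans-acting siRNAs are not in the table, so none was tested. Of 2 tested flowering genes 1 was lower under heat in Col-0 cytoplasm, and of 2 shoot meristem markers 1; these lists were too short for camera. RR3, a response regulator of cytokinin signalling (uncertain), took 10.9% of counts in Col-0 cytoplasm at 21 °C and 0.629% in Col-0 nuclei.

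Nuclear levels in tho5ab relative to Col-0 fell with the number of exons. Among genes with introns alone, 3298 genes with over 10 exons minus 4227 genes with 2 or 3 gave a genotype difference of -0.634 in nuclei at 21 °C (1.261 against 1.896, 6 of 6 libraries below Col-0) and -0.796 at 37 °C. In cytoplasm it was -0.107 at 21 °C and -0.135 at 37 °C. These values restate, on the same libraries, the medians by exon class already seen, so they are no separate test, and which property of the transcripts sets the pattern is open. Exon number also separated the fractions within each genotype. For nuclei against cytoplasm at 21 °C, median log2 differences in Col-0 were -0.15 for 1 exon and 1.52 for over 20 exons. In tho5ab they were 0.57 and 1.15.

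Other splits of the same libraries into groups of the same size were drawn, 100 per contrast with the real one included, and genes were counted by limma. In each contrast the share of splits with at least as many genes as the real one was under 0.05, not adjusted over the 18 contrasts. These are counts by limma, so they do not test the number of genes called by edgeR. For interactions with genotype, genotype labels were exchanged within fraction, temperature or both. For heat by compartment, temperature labels were exchanged within fraction. This removes the main effect too, so the splits for interactions do not test the interaction alone. Under heat the real split gave 5561 genes in Col-0 cytoplasm (highest other 5), 12556 in Col-0 nuclei (2922), 4040 in tho5ab cytoplasm (23) and 12603 in tho5ab nuclei (5208). Between genotypes it gave 8413 in nuclei at 21 °C (2044), 781 in cytoplasm at 37 °C (4) and 10925 in nuclei at 37 °C (4064). Between fractions it gave 12145 (4079) and 11646 (3601) in Col-0 and 11827 (3706) and 11561 (2027) in tho5ab, at 21 and 37 °C. Genotype by compartment gave 563 (115) and 2149 (6), genotype by heat 50 (2) in cytoplasm and 3728 (142) in nuclei, heat by compartment 2674 (13) and the interaction of all 3 154 (18). In each of these the real split alone, 1 of 100, was as large. Between genotypes in cytoplasm at 21 °C it gave 51 genes, and 2 of 100 splits were as large; the other, with 129 genes, separates the 6 libraries with high opposite-strand counts from the 6 with low counts. With a covariate for those libraries edgeR gave 657 genes there.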
